A study of Homo sapiens with 17 samples.

How the data were processed

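The series profiled where the histone variant H2A.Z sits in the genome of Caco-2/15 cells, a human colon cancer line that takes on features of absorptive enterocytes once it is confluent. Per the labels, a Flag tag had been placed by CRISPR-Cas9 in the 3′ region of 1 allele of H2AFZ (now H2AZ1, which encodes H2A.Z.1) or of H2AFV (now H2AZ2, which encodes H2A.Z.2). Chromatin from subconfluent cells and from cells kept for 7 days after confluence was precipitated with 4 µg of Flag antibody, together with 10 ng of spike-in chromatin and 1 µg of spike-in antibody. The libraries were sequenced as single reads of 85 bp. The labels name 17 samples. The 8 Flag precipitations, with 2 experiments (Exp1 and Exp2) for each of 4 groups, came with peak lists and are analysed here. The other 9 samples, precipitations of total H2A.Z and 1 input, are not analysed here. That input came from subconfluent cells with tagged H2A.Z.1, and the labels name none from postconfluent cells or cells with tagged H2A.Z.2.

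The submitters' processing notes name hg38 as the genome build and BWA and deepTools as tools. The peak caller, the control it was run against and whether the spike-in scaled any value are not given in the sources used here. There is 1 list per sample, so replicates were not pooled. In each deposited list, the score column holds 10 times the −log10 q-value as a whole number. The authors' fold enrichment column is a ratio (fold), and what it is relative to is not given in the sources used here. The deposited columns of −log10 p-value and −log10 q-value are on a −log10 scale, and the smallest deposited −log10 q-value of any list was 3.00. The last deposited column is the summit's distance from the interval's start, in bp. In tests these deposited values were used only within a list, to rank or filter its own intervals, and were not compared as levels between lists. Their ranges over lists are given only to describe the lists. A peak list holds only intervals above the authors' threshold, so no read depth, counting interval or detection floor can be derived from it, and an unlisted region may hold signal below the threshold.

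Only intervals on chromosomes 1 to 22, X and Y were used, and entries within a list were not merged. List lengths differed 2.60-fold, so each list was reduced to its 30603 intervals of highest −log10 p, the length of the shortest list, that of H2A.Z.2 subconfluent Exp2. That list was used whole, and its weakest interval had a −log10 p of 5.19, against 9.99 to 16.8 in the other 7 lists. Each interval's fold enrichment was turned into a percentile within its own list.

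Genes were the 20033 protein-coding genes of the reference annotation (GRCh38.p14). The annotation used here carries no strand, so the start of transcription could not be told from the end of the gene. For each gene, the annotated end with the higher mean percentile over all 8 lists was used, without reference to the groups, and the gene counted as occupied where an interval overlapped the 1 kb on either side of that end by at least 1 bp. Of the 13405 genes occupied in any list, 1480 (11.0%) had intervals at both ends. The word gene end below means this position, which may be the start or the end of transcription. Exons, introns and untranslated regions are not used here.

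Genes present in both lists of one group and absent from both lists of the other were counted for each pair of groups that differ in 1 factor, and genes present in all 4 lists of one side and none of the other for state and for isoform. The same was done for the 47120 regions of the merged union of the 8 lists. With 2 lists against 2 there are 3 splits, the real one included, so no share below 0.333 can be reached and no p is given. With 4 against 4 there are 35 splits. For the 10885 genes occupied in all 8 lists, the fold enrichment of the strongest interval at the gene end was ranked within each list and turned into a normal score, in units of standard deviations of a normal distribution. These scores were fitted with limma 3.58.1 (R 4.3.3) as 4 group means with 1 shared spread, and tested 2-sided with a Benjamini-Hochberg adjustment at 0.05 over the 10885 genes. A change of score says where a gene stands among these genes and not how much protein is bound.

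A total of 19 gene lists holding 500 genes were fixed for intestinal, cell cycle and chromatin functions and for markers of other cell types. They were tested with camera (preset correlation 0.01, lists with at least 5 ranked members), with 152 2-sided Fisher exact tests among the present or absent genes of the 4 pairs of groups, and per library with exact permutation tests, each adjusted by Benjamini-Hochberg. Within each list, limma p-values were also adjusted over the list alone. Per-library shares were compared by 2-sided exact permutation tests, whose smallest p for 4 against 4 is 0.0286. The likeness of the 28 pairs of lists was measured by the Jaccard index of covered bases, tested 1-sided over the 35 splits. The groups, gene lists, the tests described so far and the rule for named genes were fixed before the data were examined. Counts of other splits were in that plan for genes, for regions of the 4 pairs of groups and for the likeness of lists. Exceptions, not in that plan, are the use of gene ends, the adjustment over the list alone and the permutation tests per gene list. Other tests chosen later are named as such where they are given. That rule takes, for each pair of groups and direction, 10 genes past limma's threshold that moved the same way in both experiments and the 5 present or absent genes with the highest mean percentile. For comparisons over all lists it takes 5 of each, for each gene list up to 8 present or absent members per direction and the 4 ranked members of smallest p, the 2 strongest distal regions per direction, and always H2AZ1 and H2AZ2.

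The peak names place both H2A.Z.1 lists of Exp1 in one sequencing run, both H2A.Z.2 lists of Exp1 in another and the 4 lists of Exp2 in a further one. State is balanced within each run, while isoform and run cannot be told apart within Exp1. Each isoform was tagged in its own edited cells, so isoform and edited cell population cannot be told apart in either experiment. Across genes, the deviations of the paired lists from their group means correlated at 0.207 between states of H2A.Z.1 and at 0.158 for H2A.Z.2, against −0.0553, 0.0496, −0.00757 and 0.0310 across isoforms. The experiment number was also fitted as a replicate block, which is 1 effect common to both isoforms. Pairing within each isoform, where these correlations lie, was not fitted. The value with the block is given where it alters a call. The p-values measure only the spread between these lists, which may be technical replicates of 1 edited cell population each.

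The alternatives tried were whole lists, lists of 15301 intervals, a 2 kb window, the summit inside the window, a region at least 50% covered, the Jaccard index of gene ends, the replicate block, ranking by −log10 p, camera with an estimated correlation and leaving out each list in turn. Use of either gene end, lists of equal covered length, permutation within experiments for the likeness of lists and Fisher tests against only the genes in some of the 4 lists compared were added after seeing the data. In tests on simulated data, presence or absence in the groups' lists was recovered for 200 of 200 planted genes among 20033 in each of the 6 comparisons. Planted genes stood in every list of 1 side and none of the other, far from other gene ends, and lists were not cut to length. This recovery therefore checks only the counting, and not peaks lost at the length cut or intervals shared by neighbouring genes. With limma and 200 shifted genes among 10885, shifts of 1, 2 and 3 units were found for 0%, 45.5% and 89.5% of genes for H2A.Z.1 by state and for 0%, 40.5% and 90.0% for H2A.Z.2 by state. The same shifts were found for 0%, 49.0% and 85.5% for isoforms in subconfluent cells and for 0%, 49.5% and 89.0% in postconfluent cells. They were found for 2.0%, 95.0% and 100% for state over both isoforms, for 9.5%, 97.5% and 100% for isoform over both states, and for 0%, 5.5% and 55.5% for the difference of the changes. With camera and a list of 20 genes in the comparison by state, shifts of 0.25, 0.50 and 1 were called in 2, 20 and 20 of 20 simulations. The simulated genes were independent, so these rates may be too high for real lists with correlated or fewer members. The other comparisons were not simulated for camera. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 (exact tests), statsmodels 0.14.6 (Benjamini-Hochberg) and matplotlib 3.10.9.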

Results

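The data were 8 lists of Flag ChIP-seq peaks from Caco-2/15 cells, 2 for each of 4 groups: tagged H2A.Z.1 or H2A.Z.2, in subconfluent or 7-day postconfluent cells. The lists held 46636 and 66522 intervals for H2A.Z.1 in subconfluent cells (Exp1 and Exp2) and 56427 and 79425 for H2A.Z.1 in postconfluent cells. For H2A.Z.2 they held 55788 and 30603 in subconfluent and 39086 and 51348 in postconfluent cells. As group means these are 56579 ± 14061.5, 67926 ± 16262, 43195.5 ± 17808.5 and 45217 ± 8670.54 (SD, n = 2 each). Whole lists covered 18.5 to 46.9 Mb, with median widths of 364 to 545 bp, median fold enrichments of 4.79 to 5.95 and highest fold enrichments of 23.3 to 32.8. Read depth is not known from peak lists. All counts below come from the 30603 strongest intervals of each list unless another setting is named, coordinates are on GRCh38, and a percentile is an interval's rank by fold enrichment within its own list.

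**Figure D1:**
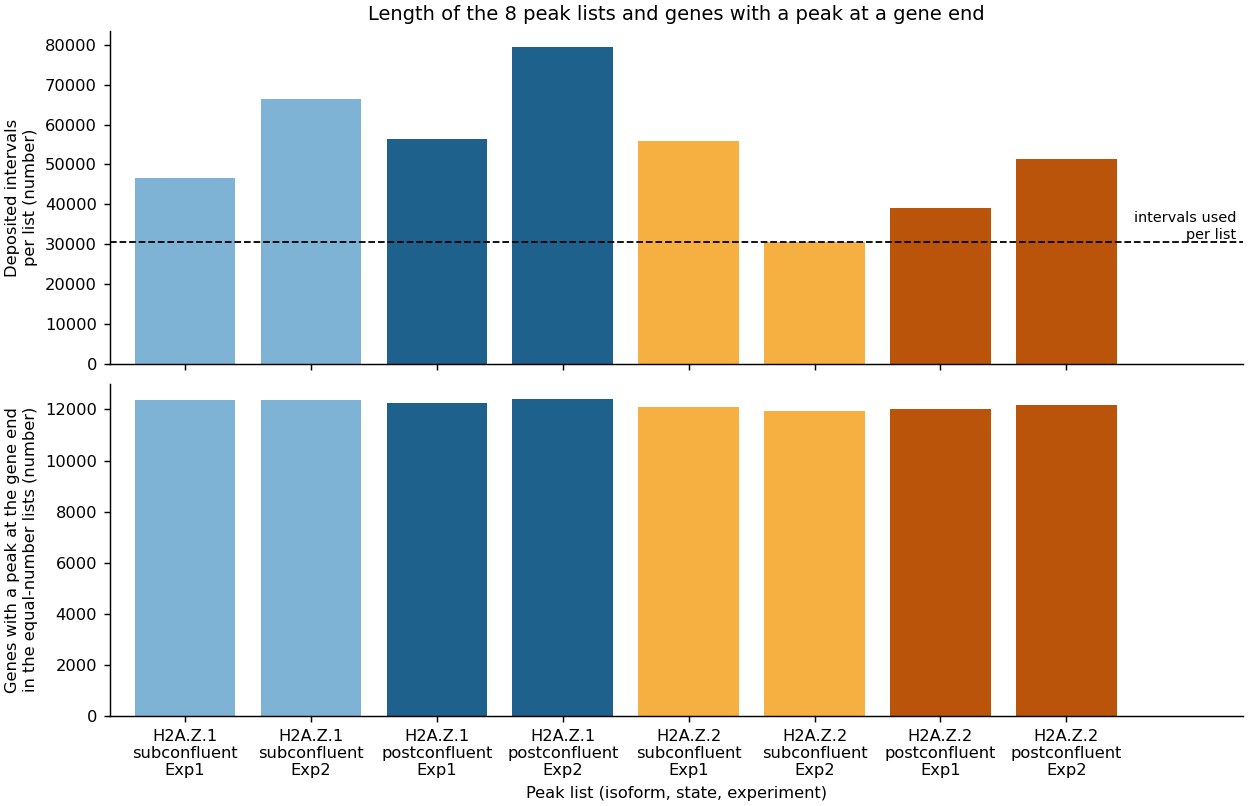
Upper bars give the number of deposited intervals in each of the 8 lists, with a dashed line at the 30603 intervals used per list, and lower bars give the number of genes with a peak at the gene end. Lists ranged from 30603 to 79425 intervals, while the genes occupied in lists of equal number ranged from 11921 to 12396.

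Tagged H2A.Z marked the ends of most cell cycle, ribosomal protein and H2A.Z machinery genes and of few marker genes of other cell lineages, in all 8 lists. A peak stood at the gene end of 11921 to 12396 of the 20033 protein-coding genes (59.5% to 61.9%) in the 8 lists, with 10885 genes (54.3%) in all 8 and 6628 in none. All 24 genes of the H2A.Z deposition and removal machinery were occupied in all 8 lists, as were 30 of 34 genes of cell cycle and DNA replication and 24 of 29 ribosomal protein genes. Each share was above that of all genes, by Fisher exact tests with Benjamini-Hochberg adjusted p = 7.05e-06, 0.000182 and 0.00712. Far fewer were occupied among secretory and tuft cell markers (3 of 30), neuronal and muscle genes (2 of 24), fibroblast markers (5 of 24), nutrient and drug transporters (6 of 25), blood cell markers (6 of 24) and liver plasma protein genes (6 of 24). For these the Fisher exact adjusted p was 7.05e-06, 2.05e-05, 0.00558, 0.0106, 0.0134 and 0.0134. The other 10 lists did not pass (Fisher exact adjusted p = 0.109 to 1). They were brush border genes (10 of 28), Wnt targets (18 of 25), hypoxia and glycolysis (18 of 25), tight junction genes (20 of 29) and growth arrest genes (12 of 17). The rest were HOX genes (25 of 39), cholesterol synthesis (11 of 24), intestinal transcription factors (15 of 25), the Notch pathway (16 of 28) and lipid absorption (12 of 22). Several hallmark genes of enterocytes, among them SI, LCT, FABP1, FABP2, SLC5A1 and KRT20, had no peak at the gene end in any of the 8 lists. In all, 11 of 28 brush border genes, 11 of 25 transporters and 3 of 22 lipid absorption genes had none in any list. These names and the test of the 19 lists were chosen after the values were seen, and genes are not independent replicates.

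The tagged genes themselves carried strong peaks in every list. H2AZ1 (chromosome 4, 99948088 to 99950275) stood at percentiles 75.9 to 93.9 with fold enrichments of 8.55 to 12.9. H2AZ2 (chromosome 7, 44826889 to 44848126) stood at percentiles 73.5 to 97.6 with fold enrichments of 9.20 to 15.1. Their normal scores differed between states by 0.26 for H2AZ1 (limma adjusted p = 0.870) and 0.29 for H2AZ2 (limma adjusted p = 0.857).

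The first comparison asks where H2A.Z.1 sits after confluence, when the cells take on enterocyte features, compared with before. The strongest H2A.Z.1 peaks found in both postconfluent lists and in neither subconfluent list stood at LTK, a receptor tyrosine kinase gene, HOXD13, a homeobox gene of posterior patterning, SH2D4B and PTGDR2, a prostaglandin receptor gene. Their percentiles were 95.1 and 97.2 for LTK (chromosome 15, 41503637 to 41513827) and 97.6 and 93.9 for HOXD13 (chromosome 2, 176087487 to 176095944). They were 94.8 and 94.8 for SH2D4B (chromosome 10, 80537902 to 80646560) and 87.4 and 87.8 for PTGDR2 (chromosome 11, 60850933 to 60855950). BCAR1, an adaptor of integrin signalling (chromosome 16, 75228181 to 75268007), followed at 68.5 and 91.4, and 1 whole subconfluent list also holds it. Present before confluence only were SESN3, a stress-induced sestrin gene (chromosome 11, 95165513 to 95232475), at 84.3 and 86.5, and CHRNB1, a muscle acetylcholine receptor subunit gene (chromosome 17, 7445061 to 7457710), at 89.5 and 66.1. So were MXD3, a repressor of the MYC network (chromosome 5, 177305499 to 177312752), at 51.3 and 75.0, and the collagen gene COL19A1 (chromosome 6, 69866556 to 70212468) at 62.9 and 63.0. GPR3, a G protein-coupled receptor gene (chromosome 1, 27392622 to 27395814), stood at 38.9 and 86.3. Whole postconfluent lists of H2A.Z.1 hold a peak in 2 of 2 for MXD3 and GPR3, in 1 of 2 for SESN3 and COL19A1 and in 0 for CHRNB1. Members of the fixed lists with a postconfluent peak only were, besides HOXD13, MYO5B, a motor of apical trafficking (mean percentile 44.2), the plasma protein gene AMBP (43.8), the nucleoside transporter gene SLC28A1 (25.6) and SERPINC1, which encodes antithrombin (21.9). Those with a subconfluent peak only included VEGFA (51.4), CSF1R and PDGFRB on 1 shared interval (39.3), HOXD10 and HOXD11 on another (23.9), SLC51B (20.04) and MEOX2 (17.5). In all, 111 genes had a peak only after and 122 only before confluence, 233 together. Of these, 29 and 8 also lacked a peak in both whole lists of the other state, and the others have one in at least 1. The highest of the other 2 splits of the 4 lists gave 154, and 3 splits are too few for a share under 0.05. The split depended on how lists were set to length: 197 after and 49 before with whole lists, 185 and 207 with lists of 15301 intervals, and 73 and 416 with lists of equal covered length, which hold 14209 to 30603 intervals.

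Among genes occupied in all 8 lists, none passed limma for H2A.Z.1 between states, with 0 calls adjusted and 750 of 10885 at an unadjusted p under 0.05. ADSS2, a purine synthesis gene that shares its interval with CATSPERE, came nearest, with a score 3.08 higher after confluence (SE 0.535, limma adjusted p = 0.0577), and with the replicate block it passed (limma adjusted p = 0.0373). Within the fixed lists, 2 of the 263 ranked members passed when adjusted over the list alone and 0 when adjusted over all genes by limma. They were BTG2, an antiproliferative gene, at −1.96 (SE 0.501, limma adjusted p over its list = 0.00975), and F2, the prothrombin gene, at −1.92 (SE 0.615, limma adjusted p over its list = 0.0308). The cell cycle genes BIRC5 and PLK1, at −1.33 and −1.24, and the microvillus gene EZR, at 1.43, did not pass either way.

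The second comparison asks the same of H2A.Z.2. After confluence its strongest postconfluent-only peaks stood at LY6S, HOXD13, NCAPD2, which encodes a condensin subunit, PKD2L1, a cation channel gene, and PTGDR2. The percentiles were 96.4 and 91.0 for LY6S (chromosome 8, 143040839 to 143076471) and 96.8 and 86.1 for HOXD13. They were 85.8 and 96.2 for NCAPD2 (chromosome 12, 6494102 to 6531955), 84.8 and 91.1 for PKD2L1 (chromosome 10, 100288149 to 100330228) and 96.2 and 73.1 for PTGDR2. Its subconfluent-only peaks were led by SMAD9, a transcription factor of BMP signalling (chromosome 13, 36844831 to 36920854), at 78.4 and 55.2, and PABPC4, a poly(A)-binding protein gene (chromosome 1, 39560816 to 39576790), at 59.3 and 65.8. Next came the formin gene FHOD3 (chromosome 18, 36297713 to 36780220) at 68.2 and 55.2 and NLRP7 (chromosome 19, 54923515 to 54966243) at 67.5 and 53.3. The orexin receptor gene HCRTR1 (chromosome 1, 31617689 to 31634492) stood at 57.1 and 62.5. Whole postconfluent lists of H2A.Z.2 hold a peak in 2 of 2 for HCRTR1, in 1 of 2 for FHOD3 and NLRP7 and in 0 for SMAD9 and PABPC4. Fixed-list members with a postconfluent peak only included HOXD13, SYP (mean percentile 67.4), CD4 (45.9), AMBP (41.6), BMP4 (30.4), ALDOC (23.9) and SLC28A1 (4.50). Those with a subconfluent peak only were LUM (56.1) and SERPINC1 (23.3). The counts were 137 genes after and 89 before confluence, 226 together against 186 in the highest other split of the 4 lists, and 38 and 26 of them also lacked a peak in both whole lists of the other state. With whole lists they were 80 and 46, with lists of 15301 intervals 215 and 158, and with equal covered length 45 and 167.

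No gene passed limma for H2A.Z.2 between states (0 calls, 633 of 10885 at an unadjusted p under 0.05). GALNT7, a gene of O-linked protein glycosylation, was nearest, 3.11 higher after confluence (SE 0.532, limma adjusted p = 0.0936), and passed with the replicate block (limma adjusted p = 0.0379). Adjusted over the list alone, 4 of 263 list members passed, and 0 adjusted over all genes by limma. These were TYMS, thymidylate synthase (1.99), BIRC5, survivin (−1.99), and MCM6, a replicative helicase subunit gene (1.82), each with limma adjusted p = 0.0244 over the cell cycle list, and the smooth muscle actin gene ACTA2 (−1.63, limma adjusted p = 0.0336 over the fibroblast list).

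Taking both isoforms together, 26 genes held a peak in all 4 postconfluent lists and in no subconfluent list, and 19 genes the reverse. Among the strongest postconfluent genes were HOXD13 (percentiles 86.1 to 97.6 in the 4 lists), PTGDR2 (73.1 to 96.2), SH2D4B (59.4 to 94.8) and the collagen receptor gene DDR1 (chromosome 6, 30880970 to 30900156, 41.3 to 75.6). Among the strongest genes with subconfluent peaks only were MXD3 (47.9 to 75.0), HCN4, a pacemaker channel gene (chromosome 15, 73319859 to 73368958, 42.8 to 63.2), SAMD5 (chromosome 6, 147508690 to 147954680, 26.1 to 74.6) and LOC124902211 (chromosome 9, 92807308 to 92809456, 29.8 to 54.6). Of the fixed lists' members, HOXD13, AMBP (mean percentile 42.7) and SLC28A1 (15.1) were among the 26 and none among the 19. In the other state's 4 whole lists, 10 of the 26 and 0 of the 19 also lacked a peak, and the others have one in at least 1. Only the 1060 genes in some of the 4 lists of each isoform could be shared by both isoforms' sets. Among these, 26 were shared after confluence against 8.66 expected of independent sets (Fisher exact p = 3.55e-08) and 19 before against 5.84 (Fisher exact p = 9.69e-07). Opposite moves were shared by 1 and 3 genes, against 5.77 and 8.76 expected (Fisher exact p = 0.0242 and 0.0382). Over the 2520 genes in some of the 8 lists, shared moves were expected for 6.03 and 4.31 genes (Fisher exact p = 4.22e-11 and 1.70e-08). Opposite moves, expected for 3.92 and 6.63, did not pass there (Fisher exact p = 0.183 and 0.155). These overlap tests were chosen after the values were seen, and genes are not independent replicates.

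**Figure D2:**
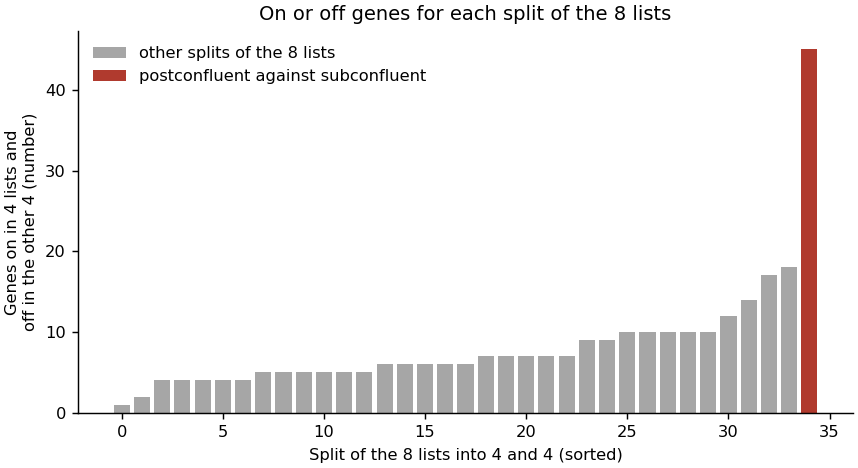
Each bar is the number of genes on in all lists of one side and off in all of the other for 1 of the 35 splits of the 8 lists into 4 and 4, sorted. The split by state gives 45 genes and the next highest split 18.

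The count of 45 by state was the highest of the 35 splits, of which the next gave 18. Of the 18 splits with 2 lists of each experiment on each side, too few for a share under 0.05, the next gave 17. HOXD13, PTGDR2, SH2D4B and DDR1 were the 4 of 26 postconfluent genes that kept this pattern at the same gene end in whole lists, lists of 15301 intervals and lists of equal covered length, while 0 of the 19 subconfluent genes did. The peak of HOXD13 lies at the annotated end next to HOXD12, and in settings that place HOXD13 at its other end (whole lists, 2 kb window, summit, either end) subconfluent lists hold peaks there too. The counts after and before confluence were 24 and 2 with whole lists, 27 and 31 with lists of 15301 intervals, and 9 and 44 with equal covered length.

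**Figure D3:**
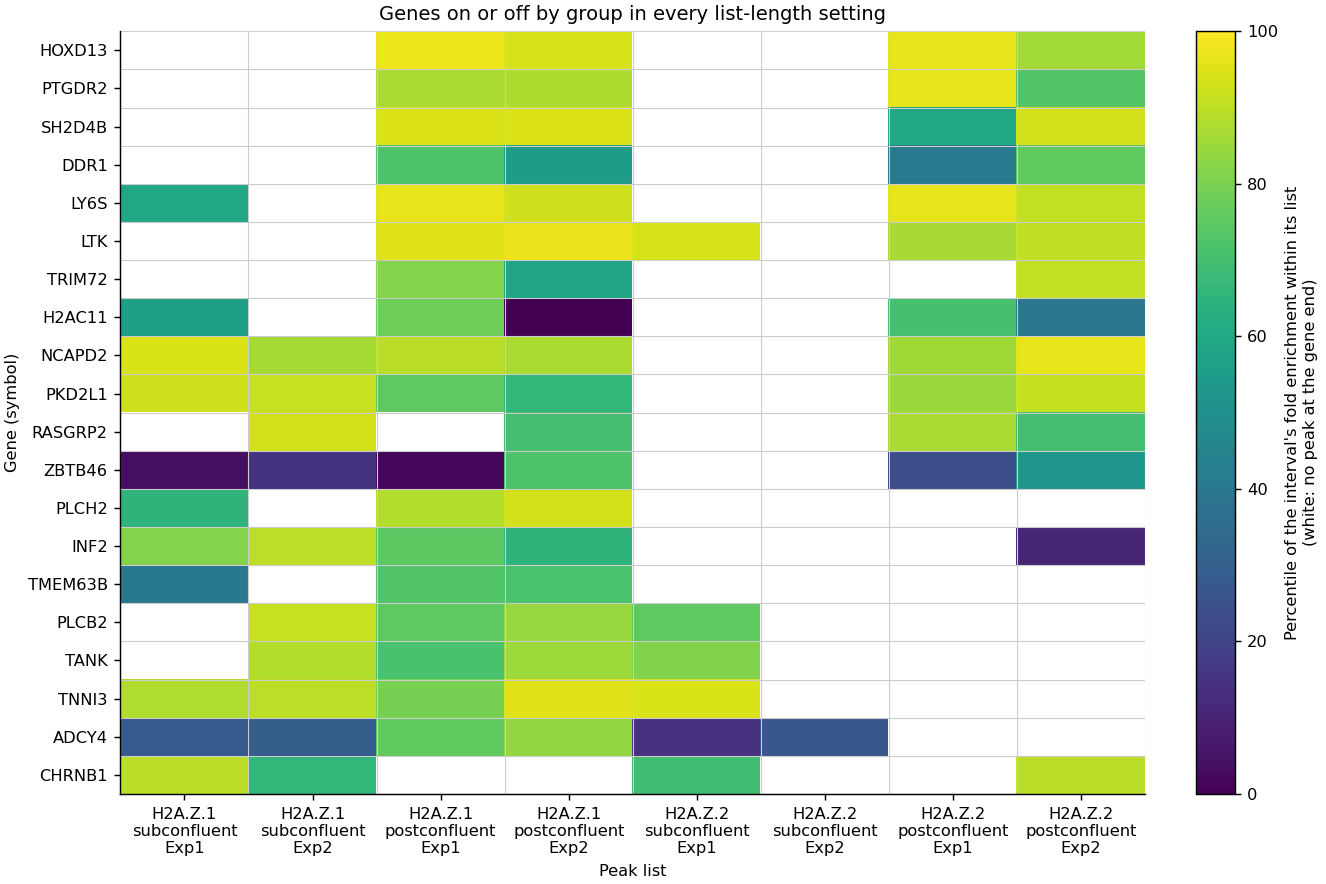
Colour gives the percentile of the peak at the gene end within its list for the 20 genes, selected after the values were seen, whose group pattern held in all 4 list-length settings, with a column for each of the 8 lists and white for no peak. HOXD13, PTGDR2, SH2D4B and DDR1 are filled in the 4 postconfluent lists and white in the 4 subconfluent lists.

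In the ranked genes, ADSS2 and CATSPERE on their shared interval rose after confluence over both isoforms by 2.43 (SE 0.379, limma adjusted p = 0.0124). So did GALNT7, by 2.14 (SE 0.376), and FAM131B, by 2.43 (SE 0.436), each with limma adjusted p = 0.0416. SPC25, a kinetochore gene, fell by 2.02 (SE 0.372, limma adjusted p = 0.0463). These 5 genes, 4 higher and 1 lower, were the calls of limma among 10885, with 995 at an unadjusted p under 0.05, and each moved the same way in both experiments. In Exp1 and Exp2 the values were 2.03 and 2.83 for ADSS2, 1.99 and 2.28 for GALNT7 and −2.53 and −1.52 for SPC25. With the replicate block 9 genes passed, the added ones being LENG9 at 1.81, CCDC74B at −1.87, the histone demethylase gene KDM5B at −1.91 and the antiproliferative gene TOB1 at −1.93 (limma adjusted p = 0.0308 to 0.0402). The count was 0 with lists of 15301 intervals and with equal covered length, and 41 when ranked by −log10 p. It was 0 without any 1 of H2A.Z.1 subconfluent Exp2, H2A.Z.1 postconfluent Exp2, H2A.Z.2 subconfluent Exp2 or H2A.Z.2 postconfluent Exp1. It was 2 without H2A.Z.2 subconfluent Exp1 and 3 without H2A.Z.1 postconfluent Exp1.

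Within the fixed lists, 5 members passed limma by state when adjusted over the list alone and 0 when adjusted over all genes. For cell cycle genes, 20 of 30 ranked members were above 0 (median 0.25). The 3 that passed over the list were TYMS at 1.79 (SE 0.401, limma adjusted p over its list = 0.00621), BIRC5 at −1.66 (SE 0.409, limma adjusted p over its list = 0.00837) and MCM6 at 1.29 (SE 0.374, limma adjusted p over its list = 0.0233). NCAM1 at −1.23 passed over the blood cell list (limma adjusted p = 0.0103) and ACTA2 at −1.21 over the fibroblast list (limma adjusted p = 0.0235). No ranked member of the other 16 lists passed. Of the brush border list, 6 of 10 ranked members were above 0, with EZR at 1.08 and DPP4 at −0.68. Of the transporters, 2 of 6 were, with the peptide transporter gene SLC15A1 at 1.25, where the median (−0.19) and the mean (0.09) differ in sign. Intestinal transcription factors had 8 of 15 above 0 (median 0.03, mean −0.13), with PRDM1 at −1.08 and CDX2 at −0.68, and lipid absorption genes 5 of 12, with APOA1 at −0.72. Wnt targets had 12 of 18 above 0 (median 0.41), with SP5 at 1.12 and EPHB2 at 0.95, while HOX genes had 8 of 25 (median −0.34), with HOXB2 at −0.91. Tight junction genes were at 10 of 20, with CLDN1 at −0.96, growth arrest genes at 7 of 12, with BTG2 at −0.96, and Notch genes at 10 of 16 (median 0.09, mean −0.05), with MAML1 at −0.92. Cholesterol genes were at 6 of 11, with TM7SF2 at 1.10 and LSS at 1.11, and hypoxia and glycolysis genes at 12 of 18, with TPI1 at 0.95. Ribosomal protein genes were at 11 of 24, with RPLP0 at −0.81, and H2A.Z machinery genes at 14 of 24, with ACTR6 at −0.67. Liver plasma protein genes were at 1 of 6, with RBP4 at −1.02, and secretory markers at 3 of 3, with SPINK4 at 0.86. Blood cell markers were at 3 of 6 (median 0.01, mean −0.14), neuronal genes at 2 of 2, and fibroblast markers at 0 of 5 (median −0.49). As sets, none of the 119 pairs of 17 lists and 7 comparisons passed camera (0 calls, 7 at an unadjusted p under 0.05). With an estimated correlation camera also gave 0 calls (1 at an unadjusted p under 0.05). The lowest camera adjusted p by state were 0.0783 for fibroblast markers (adjusted p = 0.758 with an estimated correlation), 0.117 for HOX genes (0.888) and 0.189 for Wnt targets (0.888).

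The share of each fixed list with a peak did not pass between states in any of the 19 lists, by exact permutation tests with 0 at an unadjusted p under 0.05. For lipid absorption genes it was 75.0% ± 2.62 before and 68.2% ± 3.71 after confluence (SD, n = 4, exact permutation p = 0.0857, the lowest of the 19 lists). Brush border genes were at 52.7% ± 4.49 and 50.0% ± 5.05 (exact p = 0.60), transporters at 43.0% ± 7.57 and 46.0% ± 2.31 (exact p = 0.886) and cholesterol synthesis genes at 79.2% ± 3.40 and 67.7% ± 13.8 (exact p = 0.200). In that last list FDPS and SQLE lacked a peak only in H2A.Z.1 postconfluent Exp2. Among markers of other cell types, fibroblast markers were at 37.5% ± 6.8 and 31.2% ± 4.17 (exact p = 0.286) and neuronal and muscle genes at 21.9% ± 3.99 and 17.7% ± 2.08 (exact p = 0.257). Blood cell markers were at 38.5% ± 8.59 and 35.4% ± 2.41 (exact p = 0.743) and secretory markers at 21.7% ± 1.92 and 20.8% ± 5.0 (exact p = 1). Between isoforms the lowest exact permutation p of the 19 lists was 0.0857, for Notch genes at 76.8% ± 6.84 with H2A.Z.1 and 66.1% ± 6.19 with H2A.Z.2 (SD, n = 4). Nor were fixed lists overrepresented among the genes present in one group only: of 152 Fisher exact tests, 0 passed Benjamini-Hochberg adjustment and 6 had an unadjusted p under 0.05. Against only the genes in some of the 4 lists compared, a background chosen after the values were seen, 0 passed and 3 had an unadjusted p under 0.05 by Fisher exact tests. Leaving out any 1 of H2A.Z.1 subconfluent Exp1, H2A.Z.1 postconfluent Exp1 or H2A.Z.2 subconfluent Exp2 gave 2.

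The third comparison sets the isoforms side by side in subconfluent cells. The strongest peaks of H2A.Z.1 absent from both H2A.Z.2 lists stood at PKD2L1 (percentiles 92.7 and 91.8), NCAPD2 (94.2 and 86.7) and the formin gene INF2 (chromosome 14, 104681133 to 104722535, 81.4 and 90.1). Others stood at the steroid sulfatase gene STS (chromosome X, 7147290 to 7354641, 86.1 and 68.2) and the autophagy kinase gene ULK1 (chromosome 12, 131894622 to 131923150, 68.4 and 69.1). H2A.Z.2 peaks absent from both H2A.Z.1 lists stood at LHFPL1 (chromosome X, 112630648 to 112679938, 64.0 and 62.5) and the keratin gene KRT10 (chromosome 17, 40818117 to 40822614, 51.2 and 53.5). Others stood at FGF11 (chromosome 17, 7438298 to 7444937, 54.6 and 41.3) and ADGRB3 with LOC127898563 on 1 interval (49.2 and 41.3). Whole subconfluent lists of the other isoform hold a peak in 2 of 2 for LHFPL1 and in 1 of 2 for STS, ULK1 and ADGRB3. They hold 0 for PKD2L1, NCAPD2, INF2, KRT10 and FGF11. Fixed-list members with H2A.Z.1 only were ATOH1, a transcription factor of secretory cells (mean percentile 43.3), MEOX2 (17.5), CD4 (9.70) and SLC23A1 (5.71). With H2A.Z.2 only they included SERPINC1 (23.3). The counts were 35 genes with H2A.Z.2 only and 130 with H2A.Z.1 only, 165 together against 159 in the highest other split. Of these, 6 and 28 also lacked a peak in both whole lists of the other isoform. The counts were 11 and 174 with whole lists, 75 and 182 with lists of 15301 intervals, and 92 and 26 with equal covered length, which turns the direction. Limma made 0 calls, with 400 of 10885 at an unadjusted p under 0.05 and 0 adjusted over the list alone. FOXD2 at 2.55 and CDON at 2.36 (limma adjusted p = 0.999), chosen after the values were seen, had among the largest differences, and the list members CLDN23 at 1.80 and TJP3 at −1.55 did not pass either.

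In postconfluent cells, H2A.Z.1 peaks absent from both H2A.Z.2 lists stood at the phospholipase C genes PLCH2 (chromosome 1, 2415943 to 2505532, percentiles 88.4 and 93.5) and PLCB2 (chromosome 15, 40284256 to 40307935, 75.3 and 84.6). Others stood at the cardiac troponin gene TNNI3 (chromosome 19, 55151767 to 55157732, 79.4 and 95.6), the adenylate cyclase gene ADCY4 (chromosome 14, 24318359 to 24335071, 75.4 and 83.6) and TANK, an adaptor of NF-kappaB signalling (chromosome 2, 161136963 to 161236230, 71.2 and 85.5). H2A.Z.2 peaks absent from both H2A.Z.1 lists stood at LINC02210-CRHR1 (chromosome 17, 45620346 to 45835828, 78.5 and 47.6) and the sterol isomerase gene EBP (chromosome X, 48521808 to 48528716, 64.1 and 49.8). Others stood at the ferric reductase gene FRRS1 (chromosome 1, 99703970 to 99766635, 78.5 and 31.1), and MROH6 with NAPRT on 1 interval (42.5 and 62.0). Fixed-list members with H2A.Z.2 only included EBP (mean percentile 56.9) and GATA4 (14.0), and with H2A.Z.1 only LUM (42.0) and SERPINC1 (21.9). The counts were 28 with H2A.Z.2 only and 100 with H2A.Z.1 only, 128 together, fewer than the 171 of the split by experiment. Of these, 0 and 34 also lacked a peak in both whole lists of the other isoform. Counts were 0 and 287 with whole lists, 91 and 137 with lists of 15301 intervals, and 279 and 35 with equal covered length, which again turns the direction. Limma made 0 calls, with 384 of 10885 at an unadjusted p under 0.05. One member passed when adjusted over the list alone and 0 over all genes: ESPN, an actin-bundling protein gene of microvilli, at 1.80 (SE 0.556, limma adjusted p over the brush border list = 0.0389). CHERP at 2.58 (limma adjusted p = 0.312) was the nearest over all genes, chosen after the values were seen.

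**Figure D4:**
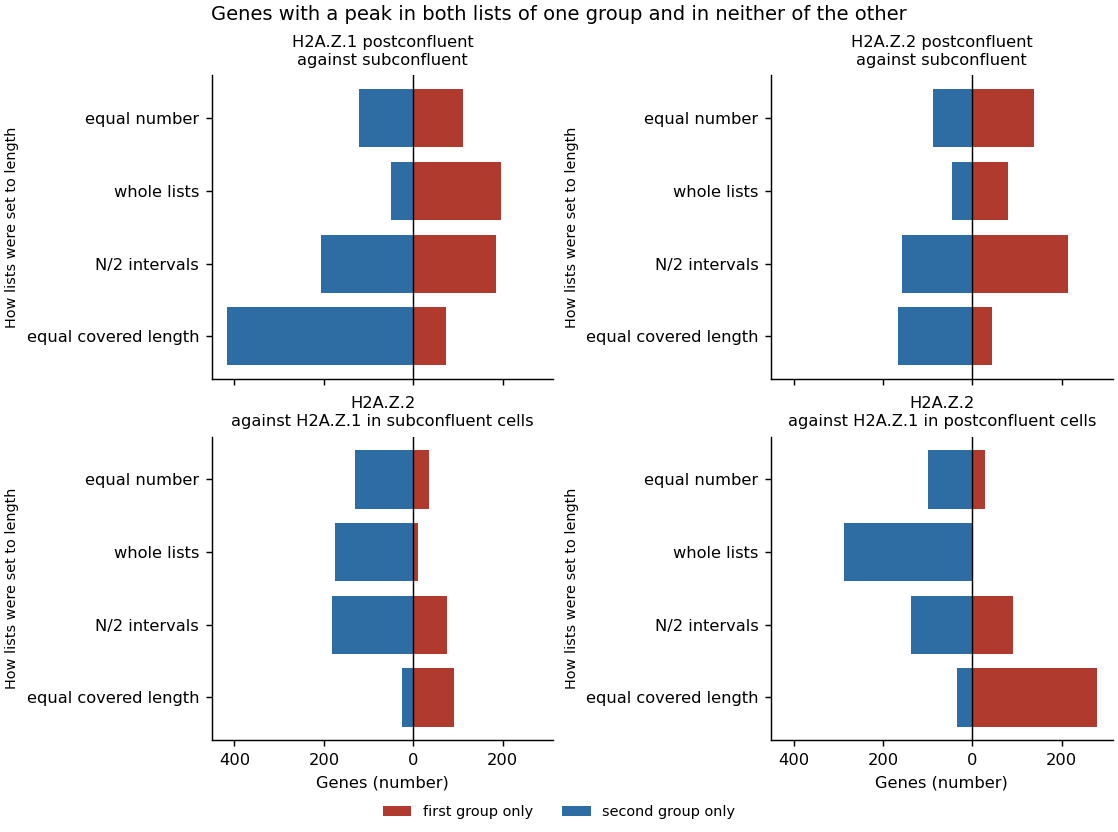
Bars give the number of genes with a peak in both lists of the first group only (red, to the right) or of the second group only (blue, to the left) for 4 pairs of groups and 4 ways of setting list length. Between isoforms in postconfluent cells the counts go from 0 and 287 with whole lists to 279 and 35 with equal covered length.

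Over both states, H2A.Z.2 alone marked 1 gene in all 4 of its lists, HGD, an enzyme gene of tyrosine breakdown (chromosome 3, 120628172 to 120682239, percentiles 9.27 to 41.9), and H2A.Z.1 alone marked 9. These were led by IFI27L2 (chromosome 14, 94127781 to 94129604, 32.2 to 65.0) and FAM86B1 (chromosome 8, 12182106 to 12194937, 33.2 to 61.7). Next came MTUS1, a microtubule-associated protein gene (chromosome 8, 17643802 to 17801521, 32.4 to 74.3), and FAM229A with TSSK3 on 1 interval (28.2 to 48.5). In the other isoform's 4 whole lists, 0 of the 1 and 1 of the 9 also lacked a peak. The 10 genes together were matched or exceeded by 10 of the 35 splits of the lists, the real one included. Counts for H2A.Z.2 and H2A.Z.1 were 0 and 20 with whole lists, 6 and 9 with lists of 15301 intervals, and 15 and 2 with equal covered length. Limma made 0 calls between isoforms (406 of 10885 at an unadjusted p under 0.05), and 1 adjusted over the list alone, CDKN2C, a cyclin-dependent kinase inhibitor gene, at 1.23 (SE 0.347, limma adjusted p over its list = 0.0230).

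Whether the change with confluence differed between the isoforms was tested as the difference of the changes. Limma made 0 calls (341 of 10885 at an unadjusted p under 0.05) and 0 adjusted over the list alone. EN2 at −3.36, DLD at 3.25 and FOXD2 at −3.49, chosen after the values were seen, came nearest (limma adjusted p = 0.876 each). Across the 10885 genes, which are not independent replicates, the change with confluence of H2A.Z.1 correlated with that of H2A.Z.2 at r = 0.263 (Spearman 0.251), and at 0.127 to 0.187 for single experiments. Between the 2 experiments of the same isoform, the change correlated at 0.167 for H2A.Z.1 and 0.141 for H2A.Z.2. The isoform difference in subconfluent cells correlated with that in postconfluent cells at r = 0.0488 (Spearman 0.0469), and at −0.107 and −0.0216 when the 2 differences came from different experiments.

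Of the 26 postconfluent genes, 5 were replication-dependent histone genes, a class chosen after the values were seen. They are H2AC20, H3C7, H3C12, H2AC17 and H2BC17, on 4 separate intervals. Of the 69 genes of the class, 10 had a peak in all 8 lists and 28 in none. With H2A.Z.1, 7 had a postconfluent peak only, and with H2A.Z.2, 10, each count including those 5, while 0 had a subconfluent peak only with either isoform.

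**Figure D5:**
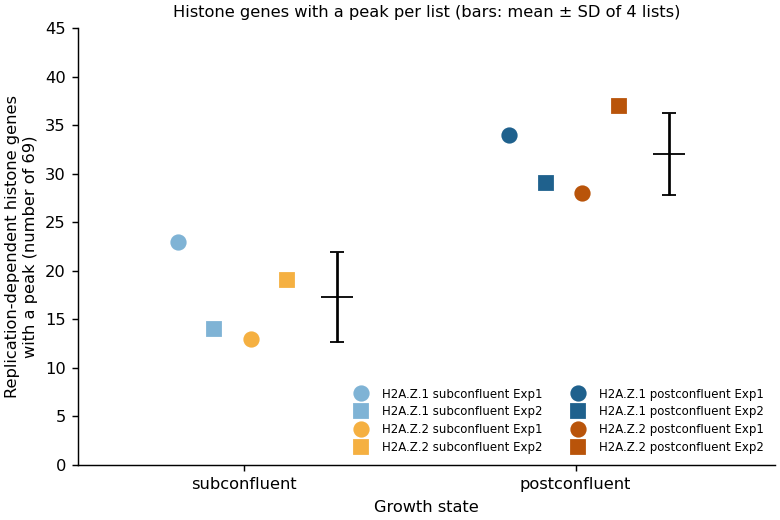
Points give the number of the 69 replication-dependent histone genes with a peak in each of the 8 lists by state, coloured by group and shaped by experiment, with bars for the mean ± SD of 4 lists. The postconfluent lists hold 28 to 37 of these genes and the subconfluent lists 13 to 23. These counts include the 5 genes that named the class, without which the ranges are 23 to 32 and 13 to 23.

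Of the lists as wholes, those of the same state were more alike than those of different states. Their mean Jaccard index was 0.628 against 0.603, a difference of 0.0253 (exact permutation p = 0.0286, 1-sided, the smallest possible for the 35 splits), and within Exp1 and Exp2 alone it was 0.0190 and 0.0378. With permutation within experiments, added after the values were seen, the exact p was 0.0556, the smallest it can give. With whole lists (0.0156, exact p = 0.171) and without H2A.Z.1 postconfluent Exp2 (0.0151, exact p = 0.171) or either H2A.Z.2 postconfluent list (exact p = 0.0857) the difference did not pass. Lists of the same isoform were not more alike (difference 0.00161, exact permutation p = 0.371, and 0.000187 and −0.00750 within Exp1 and Exp2), nor were those of the same experiment (0.0114, exact permutation p = 0.143). H2A.Z.2 lists marked fewer gene ends than H2A.Z.1 lists, 60.2% ± 0.575 against 61.6% ± 0.320 (SD, n = 4), a difference of −1.45 points (exact permutation p = 0.0286, the smallest possible), with −1.23 in Exp1 and −1.67 in Exp2. Without either H2A.Z.1 subconfluent list, or without H2A.Z.1 postconfluent Exp2, the exact p was 0.0571. With permutation within experiments the exact p was 0.0556, the smallest it can give, and with equal covered length the sign turned (2.49 points, exact p = 0.457, and 0.431 without H2A.Z.2 subconfluent Exp2, exact p = 0.857). Between states that share was 61.0% ± 0.782 after and 60.9% ± 1.10 before confluence, a difference of 0.0948 (SD, n = 4, exact permutation p = 0.914), with −0.507 in Exp1 and 0.696 in Exp2. The share of intervals within 1 kb of a gene end was 46.0% ± 1.83 after and 47.1% ± 2.63 before confluence, a difference of −1.07 (exact permutation p = 0.543), with 0.717 and −2.86 within the experiments. Between isoforms it was 47.2% ± 2.44 with H2A.Z.2 and 45.9% ± 1.98 with H2A.Z.1, a difference of 1.32 (exact permutation p = 0.429), with 0.0801 and 2.56.

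Away from gene ends, the strongest postconfluent-only region of both isoforms lay within ADAMTS13, a protease gene, on chromosome 9 from 133448120 to 133449354, 10.6 kb from the gene end. Its mean percentiles were 76.7 for H2A.Z.1 and 72.7 for H2A.Z.2. For H2A.Z.1 it was followed by a region nearest to NCS1 (chromosome 9, 130157748 to 130160217, 75.8), and for H2A.Z.2 by one within CES4A (chromosome 16, 66995688 to 66996883, 72.5). Subconfluent-only regions of H2A.Z.1 were led by one within the span of HOXC4, HOXC5 and HOXC6 (chromosome 12, 54028039 to 54029238, 71.5) and one nearest to DGCR6L (chromosome 22, 20299126 to 20299673, 67.7). Those of H2A.Z.2 were led by a region nearest to ASPH (chromosome 8, 61810133 to 61810562, 70.5). Between isoforms before confluence, H2A.Z.2-only regions lay nearest to RELL1 (chromosome 4, 37728869 to 37729865, 70.9) and CNKSR3 (chromosome 6, 154547674 to 154548851, 59.8). H2A.Z.1-only ones lay at DGCR6L (67.7) and within AGAP3 (chromosome 7, 151086898 to 151087500, 60.4). After confluence, H2A.Z.2-only regions lay within CHIC2 (chromosome 4, 54064797 to 54065195, 62.6) and CD24 (chromosome 6, 106973825 to 106974681, 52.7). H2A.Z.1-only ones lay nearest to IER5L (chromosome 9, 129289045 to 129290067, 62.0) and within ATP6V1B1 (chromosome 2, 70957817 to 70958585, 61.7). Of 47120 regions, 16878 were in all 8 lists. H2A.Z.1 had 1741 regions only after and 963 only before confluence, 2704 together against 1678 in the highest other split. For H2A.Z.2 they were 1055 and 865, 1920 against 1961. Between isoforms 484 were with H2A.Z.2 only and 866 with H2A.Z.1 only before confluence (1350 against 1753), and 320 and 1087 after (1407 against 1945). The highest other split was that by experiment in each of these 4. With whole lists the counts after and before were 7095 and 1104 for H2A.Z.1, and with equal covered length 245 and 1119 for H2A.Z.1 and 178 and 968 for H2A.Z.2, which turns the direction. Between isoforms equal covered length gave 743 with H2A.Z.2 only and 65 with H2A.Z.1 only before confluence, and 779 and 116 after, which turns it too.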

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

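Counting genes over the 35 splits was planned, with its bound set after the result was seen, while the tests over splits for regions, limma and camera and over the 18 splits balanced by experiment, of weak intervals and of the sequencing run, and the lists of equal covered length, were chosen after it was seen.

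In the lists of 30603 intervals, 4 genes moved opposite ways with confluence in the 2 isoforms, and the difference between isoforms was not tested for them. SERPINC1 (chromosome 1, 173903800 to 173917327) had peaks in both H2A.Z.1 lists only after and in both H2A.Z.2 lists only before confluence, at a mean percentile of 22.6 (14.9 to 31.6) in the 4 lists that hold it, but both whole postconfluent H2A.Z.2 lists hold a peak there too. KRT19, a keratin gene of simple epithelia (chromosome 17, 41523617 to 41528308), moved the other way at 12.4 (2.68 to 23.2). MROH6 and NAPRT, which share 1 interval (chromosome 8, 143566192 to 143572772 and 143572874 to 143578330), moved like KRT19 at 47.8 each (34.4 to 62.0). For KRT19, MROH6 and NAPRT, whole lists hold a peak in 2 of 2 postconfluent H2A.Z.1 lists and 1 of 2 subconfluent H2A.Z.2 lists, so none of the 4 genes moved opposite ways in whole lists.

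The first pattern weighed is the 26 genes with peaks in the 4 postconfluent lists only, HOXD13, PTGDR2, SH2D4B and DDR1 among them, and the 19 with the reverse. Of the 35 splits of the 8 lists, 1, the real one, gave 45 genes and the highest other 18. That argues against chance for their number only if the 8 lists are exchangeable, although they are paired by experiment. The 18 splits with 2 lists of each experiment on each side (highest other 17) are too few for a share under 0.05, so chance is not excluded there. Weak intervals near the length limit of the lists stay open: with lists of 15301 intervals again 1 of 35 splits gave as many as the 58 genes by state (highest other 23), but 4 of the 26 and 0 of the 19 are shared with that setting, and 10 and 0 lack a peak in the other state's whole lists. Covered length stays open as well, since equal covered length turns the balance to 9 and 44 but leaves 14209 to 30603 intervals per list, so length and number move together. State is balanced within each sequencing run, and the growth state itself remains a hypothesis.

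The second pattern is the lower share of gene ends with a peak in H2A.Z.2 lists. Covered length may account for it, but this is not decided: with every list covering the same number of bases the difference was 2.49 points (exact permutation p = 0.457), and 0.431 without H2A.Z.2 subconfluent Exp2 (exact permutation p = 0.857). That setting also changes the number of intervals, to 14209 to 30603 per list, so length and number cannot be told apart. The sequencing run cannot be told apart from isoform within Exp1, and within the single run of Exp2 the difference was −1.67 points, −2.52 times the pooled SD of 2 lists per isoform, too few to decide. A difference between the isoforms themselves stays open and untested. Each isoform was tagged in its own edited cells, so isoform and edited cell population cannot be told apart in either experiment.

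For the 341 regions by state (231 after and 110 before confluence), 1 of 35 splits gave as many and the highest other gave 140. That argues against chance only if the lists are exchangeable. The 18 splits balanced by experiment (highest other 83) are too few for a share under 0.05. For the 10 genes by isoform, chance cannot be excluded, since 10 of 35 splits gave as many, up to the 45 of the split by state. In a limma fit with 2 groups, 1 of 35 splits gave as many calls as the 8 by state (highest other 3, the split by experiment). That argues against chance for their number only if the lists are exchangeable, and the 18 balanced by experiment (highest other 0) are too few for a share under 0.05. Between isoforms limma made 0 calls (406 at an unadjusted p under 0.05 in the fit of 4 groups), and camera made 0 by state and by isoform. All 35 splits match a count of 0 by construction, so they test nothing there, and the highest of the other splits gave 8 limma calls and 1 camera call.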

How the results depend on the processing

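Lists of equal covered length, use of either gene end, permutation within experiments for likeness, the background of genes in some of the 4 lists and every alternative for the shared genes and the histone genes were chosen after seeing the data. Among results that answer a comparison, a count was rated as kept where its total over both directions stayed near the main total. Its direction was not part of that rating. With equal covered length, H2A.Z.2 by state was rated as kept although 137 genes after and 89 before confluence became 45 and 167. Other results were rated as kept where sign and call stayed. So rated, 17 of 28 were kept with whole lists, 15 of 28 with lists of 15301 intervals and 18 of 21 with a 2 kb window. Kept were 17 of 21 with the summit inside the window, 21 of 21 with either gene end and 13 of 28 with equal covered length. The replicate block kept 5 of 8, permutation within experiments 4 of 6 and a region at least 50% covered 3 of 4. The Jaccard index of gene ends kept 3 of 3, ranking by −log10 p 7 of 8 and camera with an estimated correlation 1 of 1. That background kept 1 of 1, and leaving out 1 list kept 149 of 224. For single genes and classes, the value was kept by 26 of 62 with whole lists, 27 of 58 with lists of 15301 intervals and 30 of 62 with a 2 kb window. It was kept by 29 of 61 with the summit inside the window, 51 of 62 with either gene end and 32 of 58 with equal covered length. Leaving out 1 list kept 460 of 496, and the replicate block and ranking by −log10 p kept 5 of 5 each. The lists' depth is not known, and the weakest interval used in H2A.Z.2 subconfluent Exp2 limits every count that needs it. Except where the construction is named, the cause was not tested.

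Lists of 15301 intervals gave more genes present in one group only (392 for H2A.Z.1 by state, 373 for H2A.Z.2 by state, 257 between isoforms before and 228 after confluence, 31 lost with both isoforms) and fewer regions (1144, 1047, 651 and 628), the latter by construction. The share of intervals near a gene end by state turned to 0.0735, that of gene ends by isoform was −1.20 (exact permutation p = 0.0857), isoform likeness −0.00105, and limma made 0 calls by state. Whole lists gave 126 genes for H2A.Z.2 by state, 287 between isoforms after confluence, 26 by state and 20 by isoform over all lists, 2 lost with both isoforms, and 8199, 2630 and 7063 regions for H2A.Z.1 by state and the isoforms before and after confluence. There gene ends by isoform differed by −4.43 (exact permutation p = 0.0571), state likeness was 0.0156 (exact p = 0.171), and camera called 2 lists by state, both lower, fibroblast markers and HOX genes (adjusted p = 0.0445 each, 0.627 and 0.685 with an estimated correlation).

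Equal covered length gave 489 genes for H2A.Z.1 by state, 314 between isoforms after confluence and 17 over both states, 9 gained and 44 lost with both isoforms, and 1364, 1146, 808 and 895 regions. It turned the share of intervals near a gene end to 4.33 by state (exact permutation p = 0.114) and −4.72 by isoform (exact p = 0.0857), that of gene ends to −3.05 by state and 2.49 by isoform, and isoform likeness to −0.00237, with 0 limma calls by state. A 2 kb window gave −0.0998 for gene ends by state, 3 limma calls for H2A.Z.1 and 1 camera call by state, fibroblast markers (adjusted p = 0.0363, 0.580 with an estimated correlation). The summit inside the window gave −0.196 by state and −0.965 by isoform (exact permutation p = 0.0571), limma calls of 1 between isoforms after confluence and 3 by state, and a share of lists with HOXD13 lower after confluence (−0.5 for H2A.Z.2, −0.25 over both), since its other end was then used. A region at least 50% covered gave 2229 regions between isoforms after confluence. With the replicate block limma made 2, 1 and 9 calls for H2A.Z.1, H2A.Z.2 and both by state, gene ends by isoform stayed at −1.45 and state likeness at 0.0253, each with exact permutation p = 0.0556 within experiments, and ranking by −log10 p gave 41 limma calls by state.

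Leaving out 1 of the lists compared raised counts of genes and regions by construction, since fewer lists must concur, while leaving out another list left them near the main count. The ranges were 231 to 680 and 223 to 571 genes by state for H2A.Z.1 and H2A.Z.2, 163 to 588 and 128 to 490 between isoforms before and after confluence, 58 to 71 by state and 15 to 26 by isoform over all lists, and 30 to 47 gained and 21 to 36 lost with both isoforms. For regions they were 2704 to 7569, 1922 to 6326, 1354 to 5936 and 1405 to 5532. Limma calls ranged from 0 to 2 for H2A.Z.1, 0 to 1 for H2A.Z.2 and 0 to 5 over both by state, and gene lists passing Fisher exact tests from 0 to 2. Gene ends differed by −0.352 to 0.403 by state and −1.65 to −1.22 by isoform. Likeness differed by −0.00992 to 0.0146 for isoform, 0.0151 to 0.0336 for state and −0.00572 to 0.0304 for experiment, the last past the threshold without H2A.Z.1 postconfluent Exp2 (exact permutation p = 0.0286).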

Other observations

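The lists of regions present by state over both isoforms with their Fisher tests, the choice of the histone class, its test without the 5 genes and the lists of equal covered length came after the values were seen.

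Distal regions with peaks in all 4 postconfluent lists only were led by those within ADAMTS13 (mean percentile 74.7) and nearest to NCS1 (70.5), CES4A (67.5), RUFY4 (chromosome 2, 218068703 to 218069393, 61.1) and KIAA0513 (chromosome 16, 85047001 to 85047870, 60.9). Those in all 4 subconfluent lists only were led by regions nearest to PDE4A (chromosome 19, 10419341 to 10420439, 55.7), SPATA13 (chromosome 13, 24270529 to 24270961, 53.9), HAS2, a hyaluronan synthase gene (chromosome 8, 121805195 to 121805510, 51.7), the differentiation inhibitor gene ID4 (chromosome 6, 19804392 to 19805259, 46.7) and ONECUT3 (chromosome 19, 1725161 to 1725707, 46.3). Of the 231 postconfluent and 110 subconfluent regions, 17.7% and 23.6% lay near a gene end, against 32.4% of all 47120 regions. Among the 110, 3 lay nearest to liver plasma protein genes, SERPINA1 (chromosome 14, 94388047 to 94389366, 42.5) and AHSG (chromosome 3, 186599531 to 186600546 and 186614468 to 186615105, 8.48 and 13.2), while AMBP of the same list had a peak only after confluence. Regions at 1 locus are not independent, and with each nearest gene counted once 0 of 38 Fisher exact tests of the lists passed Benjamini-Hochberg adjustment (lowest adjusted p = 0.181) and 3 had an unadjusted p under 0.05.

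The hypothesis tested is that replication-dependent histone genes gain H2A.Z peaks as a class after confluence. The 5 histone genes with postconfluent peaks for both isoforms named the class and cannot test it. Of the other 64, 27.0 ± 4.24 had a peak in postconfluent and 17.25 ± 4.65 in subconfluent lists (SD, n = 4), a difference of 9.75 with exact permutation p = 0.0571. Paired by isoform and experiment, it was 6 to 13 genes higher after confluence in 4 of 4 pairs (exact permutation p = 0.125, the smallest possible for 4 pairs), too few to decide, so the hypothesis stays open. The 5 genes rest on 4 separate intervals, which argues against intervals shared by neighbouring genes as their source. Covered length stays open as well. Over all 69 genes, the 5 included, the difference was 14.75, against 7.75 with equal covered length (17.75 ± 4.72 against 10.0 ± 6.38, exact permutation p = 0.114) and 14.5 with whole lists (exact permutation p = 0.0571). Without H2A.Z.2 postconfluent Exp2 it was 13.1 (exact permutation p = 0.0571). Reads shared between near-identical histone genes were not tested, so the pattern may be a change at these genes or at their paralogs.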
